A study of Escherichia coli BW25113 with 38 samples.

How the data were processed

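The series measured transcript levels in Escherichia coli K-12 strain BW25113 with miniBac-seq, a library method for small amounts of bacterial RNA. Biofilms 1 to 5 were grown from an LB preculture in a microfluidic chip until their radius was near 1 mm. Per the labels, each biofilm was sorted into 3 to 7 layers by distance from its edge, which gave 24 layer libraries between 29 and 1262 µm. The same strain was grown planktonically in M63B1 broth in a 48-well plate and sampled at 7.62, 9.8, 11.33, 12.95, 22.05, 25.28 and 28.08 h with 2 replicates, which gave 14 libraries. RNA was purified with RNAClean XP beads after lysis with lysozyme and proteinase K, per the labels' protocols.

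The authors deposited 1 table of raw gene counts, with 4531 genes and 38 libraries. Reads were processed with cutadapt 2.10 and Bowtie2 2.4.1, per the submitters' processing notes. The counting tool, the genome build, the annotation and the strand setting are not given in the sources used here. Values in the deposited count table are whole numbers whose sums differ between libraries. Each of the 38 columns was assigned to its library by its name, and 0 columns were left unassigned. Gene names were matched to the ASM584v2 annotation of strain MG1655 for names and gene types only: 4407 genes matched by symbol, 66 by synonym and 58 not at all. No count was recorded in any library for 30 genes.

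Total counts ranged from 553340 to 12796140 per layer (median 2902452) and from 440231 to 3739820 per planktonic library. Planktonic replicate 1 had a median of 2766431 counts and replicate 2 a median of 805136. Counts may include amplified copies of one molecule, so intervals and floors given in the text cover counting error only. The 22 rRNA and 86 tRNA genes were removed before library sizes were computed. The strain lacks araBAD and rhaBAD, and counts over all 38 libraries came to 0 for araB, 0 for araA, 11 for araD, 2 for rhaB, 1 for rhaA and 7 for rhaD. Its lacZ is also altered, and lacZ had 166 counts in 29 libraries. The closest pair of libraries, the replicates of 28.08 h, differed by a chi-square of 3.08 per degree of freedom over genes, so no pair was treated as a repeat of one library.

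Tests used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, libraries were scaled by TMM factors, and edgeR's quasi-likelihood test with robust dispersion was run with Benjamini-Hochberg adjustment and a threshold of 0.05. The change with distance was tested over the 24 layers as a linear term in mm with the biofilm number as a block, and curvature as a quadratic term added to it. The distance fit had a common slope and 18 residual degrees of freedom. Its SEs and calls thus take layers as the units, and differences in slope between biofilms enter only as spread between layers. The planktonic comparison set 28.08 h against 7.62 h in a fit of all 14 planktonic libraries with time as a factor, and a joint test asked for any change over the 7 times. Growth mode was tested on counts summed over the layers of each biofilm (5 sums) and over the times of each planktonic replicate (2 sums). The biological coefficient of variation was 36.5% in the layers, 22.1% in the planktonic libraries and 30.1% among the sums. Levels are in CPM, counts relative to the TMM-scaled library size, computed here from the deposited counts.

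Before the data were examined, 44 gene lists with 839 members were fixed from textbook knowledge of E. coli K-12, and all 839 members were found in the table. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with a correlation estimated for each list. Genes named in the text followed a rule fixed at the same time. For distance, planktonic time and growth mode it took the 10 largest increases and 10 largest decreases among genes that passed the test, had a mean of at least 20 CPM and moved in 1 direction in every replicate. For curvature it took the 5 smallest p-values of each sign with a mean of at least 20 CPM, and for genes of opposite direction the 5 of each kind with the largest smaller change and a mean of at least 20 CPM in both fits. It added up to 4 members with the smallest p of each list that passed, and always rpoS, csgD, csgA, fliC, tnaA, rmf, ptsG, acs, adhE and lsrB. Pseudogenes and stable RNA genes were not named.

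Each comparison was tested on simulated counts with 200 changed genes. Of 100 genes changed by a log2 of 1, the distance test recovered 76%, the planktonic test 38% and the growth mode test 51%. Of 100 genes changed by a log2 of 2, they recovered 99%, 95% and 94%. Unchanged genes made up 6.42%, 2.21% and 3.33% of the simulated calls, and camera called 2 lists along the simulated biofilm, 0 in the simulated time course and 0 between the simulated growth modes. The simulated counts were independent draws around the mean of each gene. They held no biofilm effects, no slopes that differ between biofilms and no correlated genes, so these rates may not hold in the real data. Alternatives covered RLE scaling, no count filter, DESeq2, stable RNA genes kept, shallow libraries left out, each replicate left out, other forms of the distance, the replicate number as a block, the total count as a covariate, other planktonic times and other ways to combine layers. Thinned layers, layer sets without the most distant or the rRNA-rich layer, and 22.05 h in place of 28.08 h were chosen after seeing the data.

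No label states that the planktonic replicates came from separate precultures, so p-values there measure the spread between these samples, which may be technical. Near-identical or related genes such as tufA and tufB, gadA and gadB, and argF and argI may share reads, and without a stated strand setting reads of overlapping or antisense genes cannot be told apart, so values of single members of such pairs are uncertain. Genomic coordinates were not used here.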

Results

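Transcript counts of E. coli K-12 BW25113 were obtained from 24 layers of 5 biofilms and from 14 libraries of planktonic cultures, which served as the reference. Biofilm 1 had 3 layers, biofilms 2 and 3 had 4 each, biofilm 4 had 7 and biofilm 5 had 6. Depth fell with distance: the most distant layer had the lowest total of its biofilm in all 5, and the nearest layer had 3.37, 4.50, 2.79, 7.17 and 19.6 times its counts in biofilms 1 to 5. Ribosomal RNA genes took 0.0456% to 19.0% of the counts in the layers, the highest share being that of biofilm 4 at 983 µm, and 0.0948% to 0.897% in the planktonic libraries. In a principal component analysis of the layers, the first component held 35.0% of the variance, of which distance accounted for 65.3%. The second held 11.8%, of which the biofilm number accounted for 53.3%.

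The first comparison asked how expression changed from the edge of the biofilm inwards. The lists of fatty acid oxidation, glycerol and organic acid use, general stress and toxin-antitoxin genes were higher with distance from the edge in camera, and those of ribosomal proteins, amino acid and nucleotide synthesis, iron acquisition and type 1 fimbriae lower. With an estimated correlation 0 lists passed. The steepest increases were in prpB, prpC, prpD and prpE, the operon of propionate breakdown, with log2 changes per mm of 7.10 ± 0.93, 6.90 ± 0.85, 6.89 ± 0.79 and 5.10 ± 0.57 (± SE). Transcripts of prpB averaged 15.1 ± 17.0 CPM in the nearest layers and 777 ± 500 CPM in the most distant layers (SD, n = 5 biofilms). Among the steepest decreases, metE, the cobalamin-independent methionine synthase, averaged 16210 ± 6513 CPM in the nearest and 3791 ± 2935 CPM in the most distant layers (SD, n = 5).

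In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1773 of 3955 genes changed with distance, 843 higher and 930 lower further from the edge. At least a 2-fold change per mm was fitted for 573 of the higher and 456 of the lower genes. Of the 1773 genes, 1440 (81.2%) had slopes of the fitted sign in all 5 biofilms. One slope sign in all 5 was seen in 42.5% of the tested genes, and chance alone gives 6.25%. With the log2 total count as a covariate 969 genes passed, and with only the nearest and most distant layers 1104 passed. The SEs and calls rest on layers, and slopes could differ more between biofilms: purB, with an SE of 0.28, had slopes from -3.96 in biofilm 3 to -1.21 in biofilm 1. With limma on 1 slope per biofilm, 1 gene named for distance kept its direction but no longer passed. Most named genes were chosen for small p-values or for slopes of 1 sign in all 5 biofilms. Their result thus says little about the rest of the 1773 genes.

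After the prp genes, the largest increases were in ariR, a regulator linked to biofilm formation and acid resistance (4.88 ± 0.62 log2 per mm), astA (4.65 ± 0.51), ynfP (4.64 ± 0.57), astC (4.54 ± 0.49), astD (4.49 ± 0.46) and rspA (4.37 ± 0.46). The astC, astA and astD products break down arginine by the succinyltransferase route. The largest decreases were in rcsA, an activator of capsule genes (-2.83 ± 0.63), efeO (-2.79 ± 0.46), yqgB (-2.70 ± 0.60), livJ, a binding protein for branched-chain amino acids (-2.60 ± 0.50), yceA (-2.60 ± 0.49), yfdI (-2.59 ± 0.45), metE (-2.58 ± 0.55), yhjE (-2.55 ± 0.46), the siderophore receptor gene fiu (-2.55 ± 0.61) and efeB (-2.54 ± 0.37). Adjusted p-values of these 20 genes in edgeR's quasi-likelihood test ran from 1.55e-07 for astD and rspA to 0.00163 for fiu.

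Of the 44 gene lists, 25 passed camera along the biofilm, 10 higher and 15 lower, and 0 of these passed with an estimated correlation. All 8 fatty acid oxidation genes rose, 8 also adjusted over the list alone, with a median of 3.13 log2 per mm. The fatty acid oxidation list had a camera adjusted p of 1.45e-11 (adjusted p = 0.328 with an estimated correlation). The acyl-CoA dehydrogenase gene fadE went from 265 ± 192 to 2961 ± 1978 CPM and the acyl-CoA synthetase gene fadD from 228 ± 142 to 2739 ± 1642 CPM (SD, n = 5). Of 20 genes for glycerol and organic acid use 14 rose, 14 adjusted over the list alone, with dctA, a dicarboxylate carrier, at 2.13 ± 0.25 and the glycolate oxidase gene glcD at 3.56 ± 0.42 log2 per mm. In camera the organic acid list had an adjusted p of 8.72e-09 (adjusted p = 0.328 with an estimated correlation). For acetate use and the glyoxylate shunt 5 of 10 rose, 5 adjusted over the list alone. For the acetate list camera gave an adjusted p of 0.0274, and adjusted p = 0.374 with an estimated correlation. In this list the acetyl-CoA synthetase gene acs went from 608 ± 472 to 6707 ± 4891 CPM, and yjcH (3.36 ± 0.49), actP (2.99 ± 0.50) and pck (1.22 ± 0.21 log2 per mm) rose too.

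Nitrogen starvation genes moved both ways, with 10 of 23 higher and 4 lower, and 10 and 4 adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.328 with an estimated correlation). Its 4 leading members were astB (4.04 ± 0.39), astC, astD and astE (3.78 ± 0.42 log2 per mm). In the list of peptide uptake and amino acid breakdown 11 of 28 rose and 4 fell, 11 and 4 adjusted over the list alone (camera adjusted p = 0.0290, adjusted p = 0.328 with an estimated correlation). Its leading members were the alanine breakdown genes dadA (2.98 ± 0.31) and dadX (2.59 ± 0.27), the serine deaminase gene sdaA (2.56 ± 0.27) and cstA (1.95 ± 0.25 log2 per mm).

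Among stress lists, 20 of 30 general stress genes under RpoS rose, 20 adjusted over the list alone, with a median of 1.11 log2 per mm. The general stress list had a camera adjusted p of 4.12e-07 (adjusted p = 0.328 with an estimated correlation). Its leading members were sodC (2.01 ± 0.23), yiaG (2.07 ± 0.26), the trehalose synthesis gene otsB (1.69 ± 0.24) and uspB (1.96 ± 0.29 log2 per mm). Levels of rpoS itself, which encodes the stationary phase sigma factor, were 3615 ± 321 CPM in the nearest and 4470 ± 1343 CPM in the most distant layers (edgeR adjusted p = 0.402). Of 18 envelope stress genes 9 rose and 4 fell, 9 and 4 adjusted over the list alone (camera adjusted p = 0.00177, adjusted p = 0.328 with an estimated correlation). The periplasmic proteins' genes cpxP and spy rose by 3.89 ± 0.36 and 3.53 ± 0.43, and the phage shock genes pspA and pspB by 3.40 ± 0.40 and 3.85 ± 0.49 log2 per mm. Of 22 toxin-antitoxin genes 11 rose, 11 adjusted over the list alone, led by mqsA (2.55 ± 0.29), yoeB (1.86 ± 0.22), dinJ (1.94 ± 0.23) and mqsR (2.36 ± 0.30 log2 per mm), and camera gave an adjusted p of 3.50e-05 (adjusted p = 0.328 with an estimated correlation). Of 16 SOS response genes 10 rose and 11 adjusted over the list alone, led by dinB, uvrB, polB and umuC (1.32 to 1.88 log2 per mm; camera adjusted p = 0.00132; adjusted p = 0.344 with an estimated correlation). Of 15 heat shock genes 7 rose and 1 fell, 7 and 1 adjusted over the list alone, with the chaperone genes dnaJ at 1.21 ± 0.24, clpB at 1.29 ± 0.26, dnaK at 1.05 ± 0.22 and hslO at 0.96 ± 0.21 log2 per mm. In camera the heat shock list had an adjusted p of 0.0308 (adjusted p = 0.514 with an estimated correlation).

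The lists of ribosomal proteins, translation factors, ATP synthase, the aerobic respiratory chain and glycolysis were lower with distance in camera. Of 54 ribosomal protein genes 44 fell, 44 adjusted over the list alone, with a median of -0.82 log2 per mm. For the ribosomal proteins list camera gave an adjusted p of 2.11e-08, and adjusted p = 0.344 with an estimated correlation. Examples were rpsJ (-1.64 ± 0.28), rplP (-1.38 ± 0.27), rplQ (-1.09 ± 0.21) and rpmA (-1.02 ± 0.17 log2 per mm). Of 12 translation factor genes 10 fell, and 10 fell and 1 rose adjusted over the list alone, among them infA, prfC, efp and prfB. The translation factors list had a camera adjusted p of 0.00143 (adjusted p = 0.328 with an estimated correlation). Of 9 ATP synthase genes 8 fell, 8 adjusted over the list alone, with atpD, which encodes a catalytic subunit, going from 3470 ± 393 to 1457 ± 972 CPM (SD, n = 5), and atpA, atpC and atpE also fell. In camera the ATP synthase list had an adjusted p of 0.000525 (adjusted p = 0.328 with an estimated correlation). Of 19 genes of the aerobic respiratory chain 9 fell, 9 adjusted over the list alone, led by ndh (-1.31 ± 0.23), cyoC (-2.03 ± 0.37), nuoM (-1.01 ± 0.21) and cyoD (-1.53 ± 0.32 log2 per mm), with a camera adjusted p of 0.00418 (adjusted p = 0.511 with an estimated correlation). Glycolysis and the phosphotransferase system had 10 of 17 genes lower, 10 adjusted over the list alone, among them ptsH, tpiA, pgk and gapA, which went from 15180 ± 4437 to 7325 ± 4014 CPM. For the glycolysis list camera gave an adjusted p of 0.0364, and adjusted p = 0.374 with an estimated correlation. The glucose transporter gene ptsG fell by 0.72 ± 0.20 log2 per mm.

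The 5 lists of amino acid synthesis genes were lower with distance in camera, and 0 of them passed with an estimated correlation. All 11 methionine genes fell (median -1.69 log2 per mm), 11 adjusted over the list alone, led by metA, metB, metK and metI. The methionine list had a camera adjusted p of 2.38e-06 (adjusted p = 0.328 with an estimated correlation). All 11 arginine genes fell, 11 adjusted over the list alone, with carA at -2.09 ± 0.45, argG at -1.39 ± 0.27 and argE at -0.85 ± 0.15 log2 per mm. In camera the arginine list had an adjusted p of 2.74e-05 (adjusted p = 0.328 with an estimated correlation). All 8 histidine genes fell, 8 adjusted over the list alone, among them hisC, hisD, hisG and hisB. For the histidine list camera gave an adjusted p of 0.00209, and adjusted p = 0.374 with an estimated correlation. Of 13 genes for branched-chain amino acids 11 fell and 12 adjusted over the list alone, led by ilvA, ilvI, leuD and leuC. The branched-chain list had a camera adjusted p of 1.76e-06 (adjusted p = 0.328 with an estimated correlation). Of 18 aromatic amino acid genes 15 fell, 15 adjusted over the list alone, led by aroG, tyrB, aroK and aroH. In camera the aromatic list had an adjusted p of 1.56e-05 (adjusted p = 0.338 with an estimated correlation). Of 21 purine and pyrimidine genes 19 fell, 19 adjusted over the list alone, with purB at -2.13 ± 0.28, purN at -2.16 ± 0.30, purH at -2.06 ± 0.34 and purF at -1.14 ± 0.19 log2 per mm. For the nucleotide synthesis list camera gave an adjusted p of 2.11e-08, and adjusted p = 0.328 with an estimated correlation.

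Iron acquisition had 21 of 29 genes lower, 21 adjusted over the list alone. The iron acquisition list had a camera adjusted p of 1.76e-06 (adjusted p = 0.328 with an estimated correlation). The enterobactin synthesis gene entC went from 1472 ± 377 to 355 ± 143 CPM (SD, n = 5), and entE, entB and entD fell by 1.99, 1.87 and 1.71 log2 per mm. Of 9 type 1 fimbriae genes 7 fell, 7 adjusted over the list alone, with the major subunit gene fimA at -2.19 ± 0.34, fimC at -2.01 ± 0.38, fimD at -1.65 ± 0.32 and fimF at -2.27 ± 0.48 log2 per mm. In camera the type 1 fimbriae list had an adjusted p of 0.00195 (adjusted p = 0.328 with an estimated correlation). Fatty acid synthesis had 10 of 13 genes lower, 10 adjusted over the list alone, led by accB, accC, fabB and accD. For the fatty acid synthesis list camera gave an adjusted p of 0.0240, and adjusted p = 0.344 with an estimated correlation. In cell division and peptidoglycan synthesis 14 of 25 fell and 1 rose, 14 and 1 adjusted over the list alone, led by minD, murA, murC and mraY. The cell division list had a camera adjusted p of 0.0158 (adjusted p = 0.328 with an estimated correlation).

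Lists for the matrix and for motility did not pass along the biofilm. Of 18 genes for curli, cellulose and PGA 3 rose and 2 fell, 2 and 1 adjusted over the list alone (camera adjusted p = 0.759). The curli regulator gene csgD was at 52.3 ± 8.9 CPM nearest and 44.2 ± 23.6 CPM furthest from the edge (edgeR adjusted p = 0.594), and the curli subunit gene csgA at 12.1 ± 4.6 and 8.64 ± 3.33 CPM (adjusted p = 0.232; SD, n = 5). Of 40 flagella and chemotaxis genes 6 rose and 4 fell, 5 and 2 adjusted over the list alone (camera adjusted p = 0.994), the median of 0.00 and mean of -0.05 log2 per mm differing in sign, with the flagellin gene fliC rising by 1.26 ± 0.23 log2 per mm. Of 15 TCA cycle genes 4 rose and 5 fell, 4 and 6 adjusted over the list alone (camera adjusted p = 0.906), and the median of -0.42 and mean of 0.06 log2 per mm had different signs. In the list of 7 ribosome hibernation genes 3 rose, 3 adjusted over the list alone (camera adjusted p = 0.0939), among them rmf by 1.68 ± 0.43 log2 per mm. The tryptophanase gene tnaA rose by 2.80 ± 0.44 log2 per mm, and adhE, the alcohol dehydrogenase of fermentation, was at 12900 ± 4546 and 11170 ± 5372 CPM (edgeR adjusted p = 0.886). In the mixed-acid fermentation list, which holds adhE, 6 of 13 genes rose and 0 fell, 6 and 0 adjusted over the list alone (camera adjusted p = 0.0648). The most distant layer had the lowest total count in each biofilm, alongside all of these changes, and biofilm 4 at 983 µm, with its 19.0% of rRNA counts, was among the layers fitted.

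**Figure D1:**
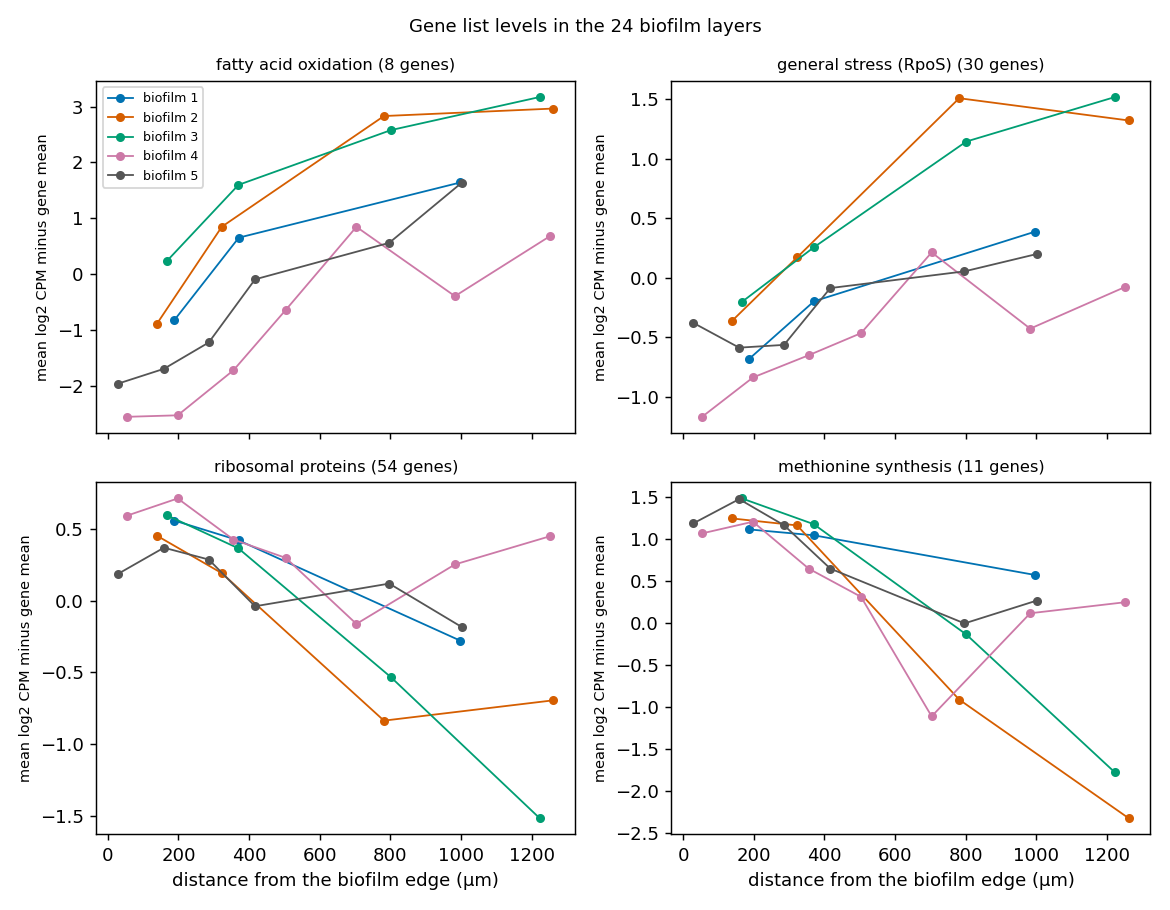
Mean log2 CPM of 4 gene lists, relative to each gene's mean, against distance from the biofilm edge in µm, with 1 point per layer and 1 line per biofilm. Fatty acid oxidation (8 genes) and general stress (30 genes) lie higher in the most distant than in the nearest layer of every biofilm, ribosomal proteins (54 genes) and methionine synthesis (11 genes) lie lower, and the lines of biofilm 4 turn between 704 and 983 µm.

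Curvature asked which genes bent between the edge and the most distant layers. The genes lsrB, lsrF and lsrG, which serve uptake and processing of the signal AI-2, were highest at middle distances: lsrB averaged 55.6 ± 30.7 CPM under 250 µm, 214 ± 78 CPM from 250 to 600 µm and 161 ± 64 CPM beyond 600 µm (SD, n = 5). Levels of lsrF were 70.7 ± 34.9, 285 ± 139 and 189 ± 67 CPM, and those of lsrG 37.3 ± 16.3, 138 ± 69 and 85.2 ± 19.0 CPM in the same order. The genes ydcS and aqpZ had a quadratic term of the same sign but kept rising, from 143 ± 121 to 460 ± 199 and 1474 ± 694 CPM and from 23.8 ± 7.6 to 52.1 ± 8.4 and 107 ± 16 CPM. In the other direction, nrfA, napA, sodB and yghJ fell from the edge to middle distances and then levelled off. Levels of nrfA were 84.1 ± 109.8, 47.1 ± 70.0 and 50.4 ± 72.7 CPM, of napA 52.6 ± 37.1, 25.7 ± 16.8 and 30.4 ± 19.2 CPM, of sodB 210 ± 102, 104 ± 54 and 119 ± 52 CPM and of yghJ 200 ± 40, 138 ± 31 and 137 ± 34 CPM. The oxidase gene cyoA fell from 1073 ± 136 to 636 ± 96 and 373 ± 139 CPM. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 120 of 3955 genes passed, 105 with a negative and 15 with a positive quadratic term, and 554 had an unadjusted p below 0.05. The 10 genes named had adjusted p-values from 0.000415 for lsrG to 0.0159 for cyoA. Without biofilm 4, 52 genes passed, of which 0 were positive. Thus nrfA, napA, sodB, yghJ and cyoA no longer passed with a positive term. DESeq2 called 186 genes, and a fit without the biofilm as a block called 1.

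The planktonic time course asked how expression changed from 7.62 to 28.08 h. The lists of fatty acid oxidation, nitrogen starvation and glycerol and organic acid use were higher late in camera, and those of aromatic, methionine and histidine synthesis, ribosomal proteins and iron acquisition were lower. With an estimated correlation the higher lists passed and these lower ones did not. The fatty acid transporter gene fadL went from 29.1 ± 18.5 to 8534 ± 34 CPM, fadH from 6.5 ± 2.9 to 4031 ± 328 CPM, tnaA from 7.19 ± 2.4 to 2550 ± 95 CPM and dctA from 21.8 ± 4.4 to 3694 ± 123 CPM (SD, n = 2). Falling genes included aroF, an enzyme at the start of aromatic synthesis, from 22850 ± 2248 to 187 ± 37 CPM, tyrA from 17780 ± 988 to 181 ± 14 CPM and metE from 25380 ± 5110 to 228 ± 15 CPM (SD, n = 2).

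With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 1981 of 3558 genes differed between 28.08 and 7.62 h, 951 higher and 1030 lower, and 2597 changed over the 7 times. Most of the difference arose late: between neighbouring times 473, 172, 451, 462, 1954 and 244 genes passed, the 1954 being those between 22.05 and 25.28 h. Between 22.05 and 7.62 h 829 genes differed, and acs stood at 141 ± 24 CPM at 7.62 h, 47.8 CPM at 22.05 h and 14520 CPM at 25.28 h.

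Other large increases were in prpB (8.94 ± 1.57 log2), glcD (8.43 ± 1.33), yqeC (8.40 ± 0.49) and the tryptophan permease gene tnaB (8.08 ± 0.49). The threonine dehydratase gene tdcB had 0 counts at 7.62 h and was at least 113-fold higher at 28.08 h against a floor of 3 counts over the group. By the ratio of counts, rhmD was 931-fold higher (95% counting interval 257 to 7700) and ddpX 444-fold higher (151 to 2160). Large decreases were also found in metA (-6.23 ± 0.42), proX, a glycine betaine binding protein (-6.24 ± 0.43), metK (-5.91 ± 0.60) and the nitrite reductase gene nirB (-5.91 ± 0.70 log2). With 1 count each at 28.08 h, metF was 221-fold lower (39.5 to 8750), psiE 116-fold lower (20.6 to 4590) and xanP 130-fold lower (23.1 to 5150). Adjusted p-values of these 20 genes in edgeR's test ran from 5.38e-15 for aroF and tyrA to 0.00155 for prpB, and dctA, named for its list and not among the 20, had 1.90e-15.

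Of the 44 lists 22 passed camera between 28.08 and 7.62 h, 9 higher and 13 lower. The 3 that also passed with an estimated correlation, at an adjusted p of 0.0471 each, were fatty acid oxidation, nitrogen starvation and glycerol and organic acid use. All 8 fatty acid oxidation genes rose, 8 adjusted over the list alone, with a median of 6.78 log2 (camera adjusted p = 3.08e-17), among them fadD (6.83 ± 0.29), fadI (7.45 ± 0.33) and fadJ (5.98 ± 0.31). In nitrogen starvation 13 of 23 rose and 1 fell, 13 and 1 adjusted over the list alone (camera adjusted p = 1.11e-06), led by astC (6.94 ± 0.34), astD (5.19 ± 0.28), astA (5.01 ± 0.29) and ddpX. For glycerol and organic acids 14 of 19 rose, 14 adjusted over the list alone (camera adjusted p = 2.01e-05), with the lactate genes lldP (4.36 ± 0.28) and lldR (3.52 ± 0.38) beside dctA (7.45 ± 0.28 log2).

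The other 6 higher lists lost the call with an estimated correlation. Acetate use and the glyoxylate shunt had 7 of 10 higher and 2 lower, 7 and 3 adjusted over the list alone, with acs, actP and yjcH between 6.11 and 6.63 log2 and maeB at 2.46 ± 0.24. In camera the acetate list had an adjusted p of 0.000188 (adjusted p = 0.139 with an estimated correlation). Of 12 genes for indole and AI-2 signals 10 rose and 1 fell, 11 and 1 adjusted over the list alone, the one that fell being luxS, the AI-2 synthase gene (-1.56 ± 0.20 log2), and the tryptophanase leader tnaC was at least 71.3-fold higher. For the signal list camera gave an adjusted p of 0.00172, and adjusted p = 0.166 with an estimated correlation. In the TCA cycle 11 of 15 rose and 2 fell, 11 and 2 adjusted over the list alone, with fumA at 4.59 ± 0.24, fumC at 3.63 ± 0.30, sdhA at 2.64 ± 0.28 and icd at -2.42 ± 0.23 log2. The TCA cycle list had a camera adjusted p of 0.00319 (adjusted p = 0.437 with an estimated correlation). Mixed-acid fermentation had 9 of 13 higher and 2 lower, 9 and 2 adjusted over the list alone, led by the fumarate reductase genes frdA, frdB and frdC and by ackA, while adhE fell by 2.57 ± 0.38 log2. In camera the mixed-acid fermentation list had an adjusted p of 0.0208 (adjusted p = 0.369 with an estimated correlation). Peptide uptake and amino acid breakdown had 12 of 28 higher and 3 lower, 12 and 3 adjusted over the list alone, led by cstA, dadA, putA and putP. For the amino acid breakdown list camera gave an adjusted p of 0.00967, and adjusted p = 0.162 with an estimated correlation. Alternative sugar uptake had 19 of 36 higher and 6 lower, 19 and 7 adjusted over the list alone, with the ribose genes rbsA, rbsB and rbsD between 4.08 and 4.85 log2 and the mannose transporter gene manY at -3.06 ± 0.26. The alternative sugar uptake list had a camera adjusted p of 0.0197 (adjusted p = 0.437 with an estimated correlation).

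All 11 methionine genes fell in the planktonic cultures, 11 adjusted over the list alone, with a median of -5.09 log2 and metC and metQ at -5.09 ± 0.32 and -3.66 ± 0.25. In camera the methionine list had an adjusted p of 5.97e-11 (adjusted p = 0.116 with an estimated correlation). All 8 histidine genes fell, 8 adjusted over the list alone, with hisD, hisC, hisH and hisB between -4.70 and -4.08 log2. For the histidine list camera gave an adjusted p of 3.39e-08, and adjusted p = 0.141 with an estimated correlation. Of 18 aromatic genes 15 fell and 1 rose, 15 and 1 adjusted over the list alone, with tyrB and pheA at -4.41 ± 0.29 and -3.71 ± 0.26 log2. The aromatic list had a camera adjusted p of 3.72e-08 (adjusted p = 0.116 with an estimated correlation). Branched-chain synthesis had 10 of 13 lower and 2 higher, 10 and 2 adjusted over the list alone, with leuC, leuD and ilvC lower and ilvB higher by 3.09 ± 0.29 log2. In camera the branched-chain list had an adjusted p of 0.00400 (adjusted p = 0.369 with an estimated correlation). Sulfur assimilation had 12 of 18 lower and 1 higher, 13 and 1 adjusted over the list alone, led by cysI, cysA, cysH and cysC, with a median of -2.99 log2, or -2.92 with the gene at 0 counts set to its bound. For the sulfur assimilation list camera gave an adjusted p of 0.000155, and adjusted p = 0.244 with an estimated correlation. Of 21 purine and pyrimidine genes 15 fell, 15 adjusted over the list alone, led by guaA, purA, purT and purL, with a median of -3.62 log2, or -3.54 with the gene at 0 set to its bound. The nucleotide synthesis list had a camera adjusted p of 0.000135 (adjusted p = 0.369 with an estimated correlation).

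Of 54 ribosomal protein genes 43 were lower at 28.08 h, 43 adjusted over the list alone, with a median of -1.74 log2 and rpsC, rplP, rplW and rpsF between -3.72 and -2.96. In camera the ribosomal proteins list had an adjusted p of 2.22e-11 (adjusted p = 0.204 with an estimated correlation). Translation factors had 6 of 12 lower and 1 higher, 6 and 1 adjusted over the list alone, led by tufB, tufA, tsf and prfB. For the translation factors list camera gave an adjusted p of 0.0419, and adjusted p = 0.437 with an estimated correlation. ATP synthase had 8 of 9 lower, 8 adjusted over the list alone, with atpD going from 3031 ± 335 to 367 ± 71 CPM (SD, n = 2) and atpG, atpA and atpF also lower. The ATP synthase list had a camera adjusted p of 2.18e-05 (adjusted p = 0.156 with an estimated correlation). Glycolysis and the phosphotransferase system had 14 of 17 lower and 1 higher, 14 and 2 adjusted over the list alone, led by eno, gpmM, ptsG and gapA. In camera the glycolysis list had an adjusted p of 0.000163 (adjusted p = 0.275 with an estimated correlation). Iron acquisition had 25 of 29 lower, 25 adjusted over the list alone, with cirA at -4.43 ± 0.26 and entE, entB and entF between -3.64 and -3.15 log2. For the iron acquisition list camera gave an adjusted p of 5.02e-08, and adjusted p = 0.0661 with an estimated correlation. Oxidative stress had 11 of 16 lower and 4 higher, 11 and 4 adjusted over the list alone, led by ahpC, sufE, sufS and oxyR. The oxidative stress list had a camera adjusted p of 0.00316 (adjusted p = 0.156 with an estimated correlation). Glutamate-dependent acid resistance had 8 of 13 lower, 8 adjusted over the list alone, with gadC going from 1546 ± 364 to 224 ± 10 CPM (SD, n = 2) and hdeB, hdeA and gadA also lower. For these 4 genes the decrease rested on the 7.62 h libraries: from 9.8 to 28.08 h mean levels went from 74.5 to 224 CPM for gadC, 89.8 to 234 for hdeB, 79.6 to 171 for hdeA and 38.2 to 332 CPM for gadA. In camera the acid resistance list had an adjusted p of 0.00535 (adjusted p = 0.437 with an estimated correlation). Between the last 2 and the first 2 times together gadA was higher, by 0.65 log2.

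General stress genes under RpoS did not pass in the planktonic comparison, with 8 of 30 higher and 6 lower, 8 and 6 adjusted over the list alone (camera adjusted p = 0.355), and their median of -0.06 and mean of 0.42 log2 had different signs. Levels of rpoS were 7004 ± 431 CPM at 7.62 h and 5545 ± 143 CPM at 28.08 h (edgeR adjusted p = 0.163). For csgD they were 105 ± 13 and 107 ± 0.49 CPM (adjusted p = 0.973), for csgA 11.7 ± 0.2 and 27.1 ± 5.9 CPM (adjusted p = 0.191), for rmf 16.5 ± 5.6 and 17.3 ± 3.8 CPM (adjusted p = 0.843) and for lsrB 17.4 ± 8.2 and 108 ± 3 CPM (adjusted p = 0.0671; SD, n = 2 for each). The flagellin gene fliC rose by 1.80 ± 0.30 log2.

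**Figure D2:**
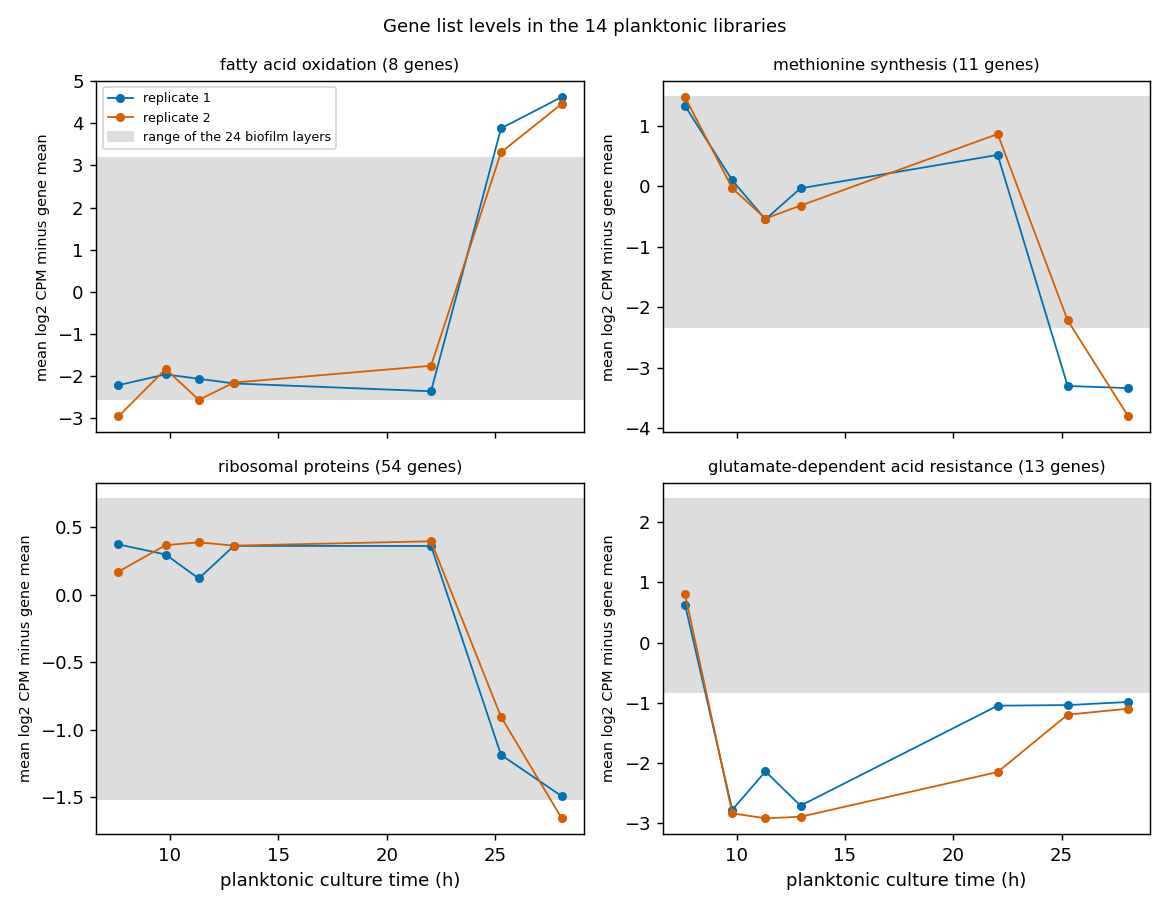
Mean log2 CPM of 4 gene lists, relative to each gene's mean, against planktonic culture time in h, with 1 line per replicate and a grey band for the range of the 24 biofilm layers. Fatty acid oxidation steps up and methionine synthesis and ribosomal proteins step down between 22.05 and 25.28 h in both replicates, and the acid resistance list lies inside the band at 7.62 h only.

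The next comparison asked how far distance from the edge went with time in a planktonic culture. Genes such as prpB, acs, fadD and astC rose in both, and metE, tyrB, rplP and entE fell in both. Of 3545 genes tested in both, 1169 passed both tests, of which 510 were higher and 573 lower in both, where independent lists would give 216.8 and 262.1. Another 44 genes were higher with distance and lower late, and 42 were lower with distance and higher late, against 236.8 and 239.9 for independent lists.

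Genes moving in opposite directions included fruB and fruK of fructose uptake, which rose by 1.38 ± 0.24 and 1.29 ± 0.25 log2 per mm but fell by 3.71 ± 0.56 and 2.04 ± 0.54 log2 in planktonic time. The genes ybgS, raiA and sdaC also rose with distance, by 1.66 ± 0.47, 1.82 ± 0.34 and 1.11 ± 0.24 log2 per mm, and were lower late by fitted changes of -2.56 ± 0.30, -1.28 ± 0.25 and -2.44 ± 0.44 log2. For raiA the fall rested on the 7.62 h libraries. The gene flu, which encodes the adhesin antigen 43, fell with distance from 5792 ± 777 to 2886 ± 1518 CPM (SD, n = 5) and rose in planktonic time from 192 ± 16 to 574 ± 26 CPM (SD, n = 2). The genes ndk, mepS, cyoA and mprA fell with distance (-1.49 ± 0.31, -1.36 ± 0.28, -1.30 ± 0.29 and -1.27 ± 0.39 log2 per mm) and rose late (1.70 ± 0.39, 1.72 ± 0.50, 1.99 ± 0.34 and 1.11 ± 0.29 log2).

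The share of one direction was 92.6% of the 1169 genes, with an odds ratio of 156 and p = 2.60e-219 in Fisher's exact test across genes, which are not independent replicates. Across genes the log2 changes had a Spearman rho of 0.638 and a Pearson r of 0.679. With 22.05 h in place of 28.08 h, an alternative chosen after seeing the data, 212 genes shared their direction and 256 had opposite directions. Without replicate 2 of 7.62 h, 52 genes had opposite directions.

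**Figure D3:**
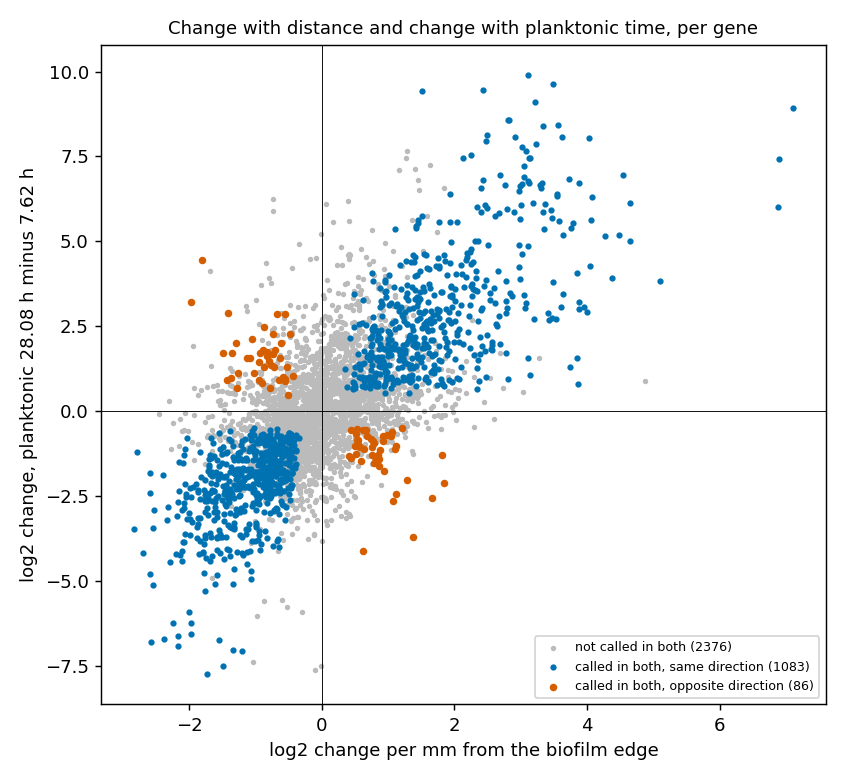
Log2 change per mm from the biofilm edge (horizontal) against log2 change from 7.62 to 28.08 h of planktonic culture (vertical), with 1 point for each of 3545 genes. The 1083 genes that passed both tests in one direction lie in the lower left and upper right, and the 86 of opposite direction in the other quadrants.

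The last comparison set the summed layers of each biofilm against the summed times of each planktonic series. Raw counts were summed, so deeper libraries weighed more. The nearest layer had 2.79 to 19.6 times the counts of the most distant one and weighed more by as much. Arginine and nucleotide synthesis genes fell with distance and organic acid genes rose, so this weighting can widen their differences between growth modes. The lists of arginine synthesis, purine and pyrimidine synthesis and glutamate-dependent acid resistance and the antigen 43 gene flu were higher in the biofilms, and dhaK, dhaL and fruB were lower. With an estimated correlation 0 lists passed between growth modes. The ornithine carbamoyltransferase gene argI averaged 126 ± 19 CPM in 5 biofilms and 3.89 ± 0.42 CPM in the 2 planktonic series (SD), and flu 4919 ± 847 and 405 ± 6 CPM. Planktonic series pool libraries by replicate number, so their SD may not measure a spread between separate cultures. The dihydroxyacetone kinase gene dhaK averaged 125 ± 16 CPM in biofilms and 764 ± 145 CPM in planktonic series, and fruB 142 ± 14 and 661 ± 185 CPM. Growth mode went together with vessel and handling, since the layers came from sorted biofilms in a chip and the cultures from wells, so these differences cannot be assigned to any one of them. The medium and age of the biofilms are not given here, so a difference in these cannot be told apart either.

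In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 407 of 4252 genes differed, 252 higher and 155 lower in biofilms. The largest increases after argI were in codB (4.83 ± 0.46 log2), ydfZ (4.71 ± 0.74), pyrB (4.55 ± 0.77), the uracil permease gene uraA (3.97 ± 0.57), pyrI (3.83 ± 0.66), flu (3.60 ± 0.26), pyrD (3.49 ± 0.47), borD (3.41 ± 0.28) and the arginine binding protein gene artJ (3.39 ± 0.33). The largest decreases were in tnaB (-3.90 ± 0.54), ibpB, a small heat shock protein (-3.44 ± 0.42), cyuP (-3.29 ± 0.28), tnaA (-3.07 ± 0.53), dctA (-2.93 ± 0.30), ynfM (-2.77 ± 0.17), dhaK (-2.61 ± 0.17), the maltoporin gene lamB (-2.24 ± 0.42), fruB (-2.22 ± 0.18) and dhaL (-2.18 ± 0.20 log2). Adjusted p-values of these 20 genes ran from 0.000145 for argI to 0.0196 for lamB. In 3 genes, flu, sodB and hycB, all 24 layers lay above all 14 planktonic libraries, and in 0 genes below. Planktonic levels of hycB were near the detection floor, at 0.878 ± 0.734 CPM against 25.4 ± 22.8 CPM in biofilms (SD; edgeR adjusted p = 0.0482). Chance would give 2.07e-08% of genes if all 38 libraries were exchangeable, which layers of one biofilm are not. In this comparison sodB was named after its values were seen.

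Some decreases depended on the planktonic stage and on how layers and times were combined. With all times kept, tnaA, dctA and lamB had positive log2 changes in biofilms in the fit on all 38 libraries and with limma on mean log2 CPM. Against 7.62 to 12.95 h alone, these genes were higher in biofilms too, by 3.47, 2.22 and 3.50 log2. That setting called 767 genes and 22.05 to 28.08 h alone called 1219, a fit on all 38 libraries called 1637, limma on mean log2 CPM called 220 and DESeq2 784, while 198 passed without biofilm 1, 73 without planktonic replicate 1 and 16 without planktonic replicate 2.

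Of the 44 lists 12 passed camera between growth modes, 7 higher and 5 lower in biofilms, and 0 of these passed with an estimated correlation. Against 7.62 to 12.95 h alone 5 of the 12 passed in the same direction, and against 22.05 to 28.08 h alone 11 did. In arginine synthesis 10 of 11 genes were higher, 10 adjusted over the list alone, with a median of 2.27 log2 and argF, argC and argD at 2.63 ± 0.24, 2.98 ± 0.33 and 2.25 ± 0.24. For the arginine list camera gave an adjusted p of 6.79e-25, and adjusted p = 0.191 with an estimated correlation. In acid resistance 12 of 13 genes were higher, 13 adjusted over the list alone, with a median of 2.03 log2 and mdtE, mdtF, gadB and gadX at 3.32 ± 0.36, 3.06 ± 0.56, 1.97 ± 0.36 and 1.11 ± 0.21. The acid resistance list had a camera adjusted p of 1.05e-12 (adjusted p = 0.500 with an estimated correlation). Of 21 purine and pyrimidine genes 12 were higher, 14 adjusted over the list alone, with purE, purM and purN at 2.12 ± 0.21, 1.93 ± 0.23 and 1.27 ± 0.17 log2. In camera the nucleotide synthesis list had an adjusted p of 9.94e-12 (adjusted p = 0.734 with an estimated correlation). Methionine synthesis had 5 of 11 higher, and 8 higher and 1 lower adjusted over the list alone, led by metK, metN, metF and metB. For the methionine list camera gave an adjusted p of 0.000997, and adjusted p = 0.500 with an estimated correlation. ATP synthase had 0 of 9 genes past the test, 4 higher adjusted over the list alone. The ATP synthase list had a camera adjusted p of 0.0165 (adjusted p = 0.851 with an estimated correlation). Type 1 fimbriae had 0 of 9, 0 adjusted over the list alone, with a median of 2.49 log2. In camera the type 1 fimbriae list had an adjusted p of 0.0197 (adjusted p = 0.851 with an estimated correlation). Anaerobic respiration had 1 of 43, 0 adjusted over the list alone, with a median of 1.85 log2 (camera adjusted p = 0.00382; adjusted p = 0.910 with an estimated correlation), and that gene was hycB.

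Lower lists included oxidative stress, with 7 of 16 genes lower and 8 adjusted over the list alone, among them the iron-sulfur cluster genes sufA, sufB, sufD and sufS between -1.16 and -0.79 log2. For the oxidative stress list camera gave an adjusted p of 0.000298, and adjusted p = 0.363 with an estimated correlation. Acetate use and the glyoxylate shunt had 3 of 10 lower, 3 adjusted over the list alone, namely maeB, ppsA and glcB, while acs was at 2414 ± 1913 and 2490 ± 574 CPM. The acetate list had a camera adjusted p of 0.00271 (adjusted p = 0.851 with an estimated correlation). Ethanolamine use had 1 of 16 lower, eutC, 1 adjusted over the list alone. In camera the ethanolamine use list had an adjusted p of 0.000622 (adjusted p = 0.191 with an estimated correlation). Alternative sugar uptake had 9 of 36 lower, and 15 lower and 1 higher adjusted over the list alone, among them rbsB, lamB, srlD and galK. For the alternative sugar uptake list camera gave an adjusted p of 8.42e-07, and adjusted p = 0.768 with an estimated correlation. Glycerol and organic acid use had 2 of 20 lower, dctA and glcF, 11 adjusted over the list alone. The organic acid list had a camera adjusted p of 0.000110 (adjusted p = 0.768 with an estimated correlation). These last 2 lists were higher in biofilms, with medians of 0.72 and 2.08 log2, against 7.62 to 12.95 h alone. The sigma factor gene rpoS was lower in biofilms by a fitted -0.67 ± 0.17 log2 (edgeR adjusted p = 0.0475). Curli, cellulose and PGA genes did not pass, with 0 of 19 called and 0 adjusted over the list alone (camera adjusted p = 0.983, direction down, with a median of 0.08 and a mean of 0.06 log2), and csgD was at 60.8 ± 14.8 and 98.1 ± 28.7 CPM (edgeR adjusted p = 0.132). The genes fliC, adhE, lsrB, csgA, ptsG and rmf did not pass either, with edgeR adjusted p-values from 0.444 to 0.872.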

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

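Of the tests in this part, the one on steps of rising depth and the one on shuffled distances were set before their results were seen, and those on the thinned layers, the planktonic stage, the handling and the order of the layers of biofilm 4 were chosen afterwards. The fit with the depth covariate was planned, and its use to weigh depth as the whole cause was chosen afterwards.

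The change with distance went together with falling depth, since the most distant layer was the shallowest in each biofilm. An effect linear in the log2 total count, as the whole cause, is argued against by the covariate fit. There 934 of the 1773 genes still passed in the same direction. Effects of depth in any other form are not covered by that covariate. Chance in the order of the layers is argued against. Only 1 of 100 orders of the distances within biofilms, the real one, called as many as 1773 genes, and the highest other called 0. Shuffling cannot separate distance from other quantities that run with it, such as the total count. Over 5 steps where the total rose with distance, by 1.27 to 2.46 times, the share of genes that moved with a gradient fitted without that biofilm was 82.3%, 55.4%, 64.9%, 69.0% and, from 704 to 983 µm in biofilm 4, 21.2%. That last step went the way expected if depth were the cause, and the other 4 did not. With the covariate 969 genes passed in place of 1773, and with all layers thinned to the smallest total 1523 passed, 1446 of them among the 1773 in the same direction. Thinning equalises total counts and no other property of a shallow library, so a part played by depth and a spatial one cannot be told apart. Spatial biology stays a hypothesis.

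Arginine synthesis and acid resistance genes were higher in biofilms than in planktonic cultures, although neither list passed camera with an estimated correlation (adjusted p = 0.191 and 0.500). For arginine synthesis the means of 5 of 5 biofilms lay above the highest planktonic library. They ran from 0.161 to 1.21 against -0.623 (mean log2 CPM relative to each gene's mean). The planktonic libraries of the 7 sampled times thus did not reach the biofilm means, although 8 of 14 lay above the lowest layer. The difference was found in these same libraries, and stages before or between the sampled times were not measured. An unsampled planktonic stage and growth mode therefore cannot be told apart for arginine synthesis. For acid resistance 3 of 5 biofilm means lay above the highest planktonic library, at 7.62 h, so stage and growth mode cannot be told apart for this list: the biofilm means of 0.338 to 1.53 span the 0.806 of that library. Sorting and the chip may also contribute to both lists, and 0 libraries separate handling from growth mode, so these cannot be told apart. A biological effect of biofilm growth stays open and untested.

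In biofilm 4 the layer at 704 µm looked more distant than that at 983 µm. The mean change along genes called without biofilm 4 was 0.643 at 704 µm, 0.124 at 983 µm and 0.309 at 1252 µm. A difference in total count alone is argued against as the cause. In 20 of 20 draws thinned to the smallest total the 704 µm layer stayed above, by 0.465 to 0.483 against 0.519 unthinned. Thinning to 547716 counts hardly changed the 704 µm library, which had 635750, and equalised no other property of a shallow library. Other effects of low depth thus stay open. Exchanged labels could give this order, but 1 of 6 steps went against distance as labelled and 1 of 6 with the 2 exchanged, beside 1 of 5 in biofilm 5. The exchange thus left the number of such steps as it was. An exchange, another effect of low depth and a real local difference cannot be told apart. The 983 µm library also held the highest rRNA share, 19.0% of its counts.

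Slopes of 5 genes and the level of 1 gene stood apart from those of the other 4 biofilms by a gap of more than 0.71 of the range of all 5, among 135 groups of slopes and 56 groups of levels, where chance picks about 1 group in 20. The slope of mqsR in biofilm 5 was 3.83 log2 per mm against 1.76 to 2.01 in the others, and that of pspB 5.46 against 2.91 to 3.47. In biofilm 5 the slope of rmf was 0.208 against 1.46 to 1.76, and that of ptsG -1.03 against -0.713 to -0.642. The slope of murC in biofilm 3 was -1.91 against -0.775 to -0.51. Levels of tnaA in the sum of biofilm 4 were 18.5 CPM against 73.3 to 100 CPM in the others.

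Ribosomal RNA genes, which were left out of the comparisons except where an alternative kept them, took more of the counts in 8 layers than in any planktonic library (0.897%). The shares were 1.41% in biofilm 1 at 188 µm, 1.40% in biofilm 2 at 1262 µm, and 1.57%, 2.09%, 5.05% and 3.17% in biofilm 3 at 1223, 802, 370 and 167 µm. In biofilm 4 they were 19.0% at 983 µm and 1.34% at 704 µm.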

How the results depend on the processing

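Of the alternatives named here, thinned layers, layers left out for their distance or their rRNA share, and 22.05 h in place of 28.08 h were chosen after seeing the data. For named genes, 4883 recomputed values kept their direction and side of the threshold, 219 kept the direction but no longer passed, 15 passed where they had not, and 51 turned direction, and 27 sign changes between values that passed no threshold are counted as kept. For named lists, 531 kept both, 87 no longer passed and 2 turned. Genes changing with distance numbered 1773, and 1104 with only the nearest and most distant layers (10 libraries, of which 1077 were among the 1773), 969 with the log2 total as a covariate (934 among them), 1320 without the most distant layers and 1523 with all layers thinned to 547716 counts (1446 among them). Leaving out each biofilm gave 1364 to 1770 genes with distance and 52 to 114 with curvature. Curvature gave 186 genes with DESeq2 and 1 with no replicate block, a fit in which differences between biofilms stay in the spread. The planktonic comparison gave 1604 to 1745 genes without each of the 4 libraries, and the test of any change 2488 to 2582 without each of the 14. The lone library left in such a group was assumed to vary like the others. Shared directions numbered 874 to 1115 and opposite ones 52 to 82 when a biofilm or library was left out. Growth mode gave 16 to 455 genes without each biofilm or planktonic series, 767 against 7.62 to 12.95 h, 1219 against 22.05 to 28.08 h, 784 with DESeq2, 1637 in a fit on all 38 libraries and 220 with limma on mean log2 CPM, and without a planktonic series a single sum remains on that side. Lists that passed numbered 22 to 26 along the biofilm, 19 to 22 in planktonic time and 12 to 15 between growth modes when a replicate was left out. With an estimated correlation they numbered 0, 3 and 0, where the wider variance allowed for correlated members is part of that setting, and between growth modes 23 lists passed against 22.05 to 28.08 h, with 11 of the 12 in the same direction, and 14 against 7.62 to 12.95 h, with 5 of the 12. Scaling by RLE and no count filter left each count within 1.5 times. Keeping the stable RNA genes and leaving out the 2 shallow libraries (biofilm 4 at 1252 µm with 547716 and 28.08 h replicate 2 with 435974 counts) did so for the genes with distance, with curvature, in planktonic time and between growth modes, and were not run for the lists or for shared and opposite directions. Unless stated, the cause of these differences was not tested.

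With 22.05 h in place of 28.08 h, 829 genes differed from 7.62 h, 212 shared the direction of the distance change and 256 opposed it. Log2 changes that turned positive were metF 0.70, psiE 0.0905, sdaC 0.12, rplP 0.75, rpsF 0.22, cysI 1.84, cysA 0.77, cysH 1.43, cysC 0.77, hisD 0.0643, hisH 0.20, tyrB 0.46, pheA 0.33 and adhE 0.14. Those that turned negative were prpB -0.55, tnaB -0.18, ndk -1.08, fumC -0.42, sdhA -0.86, acs -1.60, yjcH -1.56, maeB -0.25, frdB -0.21, frdA -0.0362, astC -1.11, astD -1.18, astA -0.91, ilvB -0.89, rbsD -0.34, fadJ -0.29, lldP -0.0374, lldD -1.13, lldR -0.75 and cstA -0.0812. Between the last 2 and the first 2 times gadA turned to 0.65. Against planktonic times of 7.62 to 12.95 h, biofilm minus planktonic turned to 2.25 for tnaB, 3.47 for tnaA, 2.22 for dctA, 3.50 for lamB, 1.24 for rbsB, 0.57 for srlD, 0.80 for glcF and 4.29 for acs, and to medians of 0.72 for alternative sugar uptake and 2.08 for glycerol and organic acid use. In the fit on all 38 libraries it turned to 0.74 for tnaA, 0.25 for dctA, 1.64 for lamB and 2.26 for acs, and with limma on mean log2 CPM to 0.56, 0.20 and 1.49 for the first 3. Against 22.05 to 28.08 h sufA turned to 0.29. These settings compare other times or weight times equally, and the cause was not tested further.

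Planktonic replicate 1 had a higher total count than replicate 2 at each time (medians 2766431 and 805136), so the number marked a difference in depth. Over 21 pairs of times the deviations of same-numbered libraries had correlations from -0.0751 to 0.153 (median 0.00852), with 4 above 0.1. Libraries thus did not all correlate best with their own number. The 2 planktonic sums of the growth mode test may therefore not stand for 2 separate cultures. With the replicate block 1991 genes differed between 28.08 and 7.62 h, 2600 changed over time, 21 lists passed, 1090 genes shared the direction with distance and 87 opposed it. In simulated counts the planktonic test recovered 38% of genes changed by a log2 of 1, so changes of that size can be missed there.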

Other observations

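The tests of opposite genes at other times and of likeness to planktonic times were chosen after the values per time had been seen.

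The largest planktonic step was short: 946 genes rose and 1008 fell in the 3.23 h between 22.05 and 25.28 h, while 462 genes changed in the 9.1 h before it. Between 22.05 and 25.28 h the dicarboxylate carrier gene dctA went from 63.2 to 11740 CPM, fadL from 37.9 to 5488 CPM and tnaA from 18.3 to 3736 CPM, and aroF went from 19300 to 178 CPM (means of 2). The sulfate assimilation genes cysI and cysH were higher at 22.05 than at 7.62 h, by 1.84 and 1.43 log2, before they fell to 17.3 and 12.1 CPM at 25.28 h. Among lists not yet described, phosphate starvation had 8 of 16 genes higher and 4 lower late, 8 and 4 adjusted over the list alone (camera adjusted p = 0.330), and the SOS response 8 of 16 higher and 2 lower, 8 and 2 adjusted over the list alone (camera adjusted p = 0.460). Along the biofilm, multidrug efflux had 6 of 18 higher and 3 lower, 6 and 3 adjusted over the list alone (camera adjusted p = 0.434).

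Slopes with distance differed between the 5 biofilms in 137 of 3955 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 99 of which also changed with distance in the common fit, and 536 had an unadjusted p below 0.05.

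One hypothesis was that the 86 genes of opposite direction reflect the 7.62 and 28.08 h libraries alone. At 25.28 against 9.8 h, in other libraries, 70.9% kept their planktonic direction (95% exact interval 60.1 to 80.2, genes taken as independent), which argues against it for the set, beside 96.6% of the genes of shared direction. A second was that they reflect the change between 22.05 and 25.28 h alone. At 22.05 against 9.8 h 68.6% kept their direction (57.7 to 78.2, genes taken as independent), beside 56.4% (53.4 to 59.4) of the genes of shared direction. Both shares count signs only, so they do not measure how large a part that step had. For the set, the 68.6% argues against that step as the only change. Single genes departed from this: raiA was at 1128 CPM at 9.8 h and 1356 CPM at 25.28 h, its fall resting on 3168 ± 1511 CPM at 7.62 h (SD, n = 2), and fruB was at 558 CPM at 9.8 h and 750 CPM at 22.05 h. For part of the set, the opposite directions may belong to a slower planktonic change. How many genes that covers cannot be read from signs, and it was not tested in separate cultures.

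Whether layers further from the edge resemble later planktonic cultures was left open. The Spearman correlation across 3545 genes with the 28.08 h profile minus that with the 7.62 h profile rose with distance in 5 of 5 biofilms, by 0.206, 0.293, 0.294, 0.139 and 0.23 per mm. The same libraries gave the shared directions with distance and time, so this rise restates them and is no separate support. The difference stayed below 0 in the most distant layers of biofilms 1, 4 and 5, at -0.0592, -0.13 and -0.0299, and 14 of the 24 layers were closest to 7.62 h, 3 to 28.08 h and 1 to 25.28 h. Margins could be small, as in biofilm 1 at 371 µm with 0.921 for 7.62 h and 0.913 for 22.05 h. The 28.08 h libraries (1340266 and 440231 counts) were also shallower than those of 7.62 h (3739820 and 1325805). These references thus differed in depth as well as in time. Genes are not independent replicates, and depth fell along the same axis.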
